A study of Mus musculus with 12 samples.

How the data were processed

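Bulk RNA-seq libraries were made from the hippocampus of 12 male mice with the App NL-G-F knock-in, with or without Trem2 knockout, at 3 or 9 months of age (4 groups of 3 libraries, each from its own mouse identifier). Per the labels' protocols, total RNA was extracted with a column kit, its quality was checked on a TapeStation, and libraries were prepared with the SMART-Seq mRNA LP kit. The deposited table holds raw read counts per gene for each library: the authors deposited integer counts without normalisation, as the values themselves show. The submitters' processing notes name STAR 2.7.10a, featureCounts 2.0.3, R 4.2.0 and DESeq2 1.36.0 and the genome build GRCm39, without giving the role or settings of each. The strand setting, the annotation release and the treatment of reads that map to several genes are not given in the sources used here, so counts of near-identical genes (the H2 genes, C4a and C4b, Amd2 and Amd1, the haemoglobins) and of overlapping or antisense genes are uncertain.

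The table holds 56980 gene identifiers, of which 38139 have a count in at least 1 library. Symbols came from a reference annotation of another mouse build (GENCODE M21 on GRCm38), which matched 52073 identifiers; the 4907 others hold at most 0.252% of the reads of a library. That annotation was used only for symbols and for which genes lie near Trem2, and no coordinates are given. Total counts per library ran from 14627892 to 24594655, and 3 counts, the upper limit that a count of 0 allows, correspond to 0.122 to 0.205 CPM (counts relative to library size). This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

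Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 19152 of them, and libraries were scaled by the trimmed mean of M-values. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, robust, R 4.3.3) on a model with 1 term per group over all 12 libraries, with 8 residual degrees of freedom and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. The 5 comparisons were Trem2-KO against App-KI at 3 and at 9 months, 9 against 3 months within each genotype, and the interaction of age and genotype. CPM values in the text use the scaled library sizes, and scores per library are means of log2 CPM over a list.

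In all, 40 gene lists were fixed from textbook knowledge before the data were examined. They cover microglia (DAM TREM2-dependent, DAM stage 1, homeostatic, pan-microglia), immune responses (interferon response, class I and class II presentation, complement), glial responses (reactive astrocyte, plaque-responsive oligodendrocyte), organelles and metabolism (lysosome, lipid handling, cholesterol synthesis, glycolysis, TCA cycle, nuclear OXPHOS, mitochondrially encoded, cytosolic ribosomal proteins, unfolded protein and heat shock), neurons (immediate early genes, synapse, excitatory neuron, inhibitory neuron, dentate granule, CA1, CA3), risk genes for Alzheimer's disease, other cell types (astrocyte, myelinating oligodendrocyte, oligodendrocyte precursor, endothelium, mural cells, meningeal and perivascular fibroblast, border macrophage and monocyte, T and NK cell, erythroid), tissue that dissection could carry along (choroid plexus and ependyma, thalamus and habenula, striatum) and the TREM family. Each list was tested against the other genes with camera (limma 3.58.1) with the preset correlation of 0.01 and again with an estimated one, over 39 lists per comparison, and with fry. Some lists share members; for example 10 of the 22 pan-microglial and 12 of the 34 lysosomal genes are in another list.

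The genes named in the text follow a rule written before the data were examined: Trem2, App and the TREM family, then for each comparison up to 12 called genes with the highest and 12 with the lowest log2 fold change, with an average log2 CPM of at least 1, a proper symbol and no overlap between the libraries of the groups compared, and for each list described the 4 members with the smallest p and up to 3 abundant members that were not called. Some items that fall under this rule are not reported here. Genes named outside it are said to have been chosen after their values were seen. The comparisons, the threshold and the alternatives not marked as later choices were also fixed at that point.

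The test was tried on simulated counts with 200 changed genes. At log2 changes of 0.5, 1 and 2 the share recovered was 53.7%, 65.7% and 93.9% for genotype at 3 months (18851 genes), 52.2%, 65.7% and 90.9% for genotype at 9 months (18837 genes), 37.3%, 64.2% and 98.5% for age in App-KI (18821 genes), 52.2%, 74.6% and 93.9% for age in Trem2-KO (18829 genes), and 37.3%, 65.7% and 83.3% for the interaction (18864 genes). Unchanged genes called numbered 14, 12, 13, 4 and 14. Beside them, 36, 44 and 62 changed genes were recovered at these sizes for genotype at 3 months. For age in Trem2-KO they were 35, 50 and 62, and for the interaction 25, 44 and 55. Except for age in Trem2-KO, unchanged genes made up a larger share of the simulated calls than the adjusted p threshold aims for. Calls in the real data may likewise hold more false ones than that threshold implies.

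The alternatives were DESeq2 (version 1.42.0), size factors of DESeq2's kind or library size alone in place of the trimmed mean, no filter, a stricter filter (30 counts in 3 libraries), a fit of the compared groups alone, limma-voom with quality weights, a least log2 change of 0.5, a fit that is not robust, 1 surrogate variable (sva 3.50.0), leaving out each library in turn, and a 10 Mb window around Trem2. Chosen after seeing the data were a choroid plexus score or a meningeal fibroblast score per library as a covariate, and leaving out the 3 libraries with the lowest choroid plexus score. Other splits of the libraries numbered 10 per comparison of 2 groups and 100 drawn for the interaction. No library was left out of the main analysis, and no batch is given in the labels. TREM family genes other than Trem2 were left out of the tests because of low counts.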

Results

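Gene expression was measured by bulk RNA sequencing of the hippocampus of 12 male mice, 1 library per mouse. All mice carried the App NL-G-F knock-in, a humanised and mutated amyloid precursor protein allele that leads to amyloid-β deposits, and 6 of them also lacked Trem2, a lipid-sensing receptor that microglia use to respond to plaques. The 4 groups of 3 mice were App knock-in at 3 months, App knock-in at 9 months, App knock-in with Trem2 knockout at 3 months and App knock-in with Trem2 knockout at 9 months, called App-KI and Trem2-KO. No mouse without the App knock-in was sequenced, so age and amyloid load cannot be separated. In App-KI mice the total counts of the 3 libraries were 24594655, 17591509 and 20574446 at 3 months and 18846482, 18646622 and 15360564 at 9 months. In Trem2-KO mice they were 14627892, 22930440 and 20907281 at 3 months and 22417397, 20941868 and 18750835 at 9 months. A count of 3 corresponded to 0.122 to 0.205 CPM (counts relative to library size). Principal component 1 held 24.6% of the variance and component 2 held 17.8%. Markers of the choroid plexus, a tissue next to the hippocampus, varied within groups: their mean log2 CPM was 1.98 in App-KI 3-month replicate 1, 1.54 in App-KI 9-month replicate 2 and 2.17 in Trem2-KO 9-month replicate 3. The group means were 3.51 and 3.76 in App-KI at 3 and 9 months, and 4.42 and 4.65 in Trem2-KO at 3 and 9 months. Markers of meningeal and perivascular fibroblasts lay at 4.58 or above in the 3 Trem2-KO libraries at 9 months and at 4.11 or below in the other libraries. Most log2 fold changes are given with a standard error from the model over all 12 libraries. It was derived from the F statistic of the test and the change before edgeR's moderation towards 0. The printed changes are moderated, so for genes with few counts the standard error belongs to a somewhat different estimate.

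Trem2 itself was lower in every Trem2-KO library than in every App-KI library of the same age. Its level was 9.19 ± 1.15 CPM (SD, n = 3) in App-KI and 1.98 ± 0.165 CPM in Trem2-KO at 3 months, and 52.7 ± 2.90 CPM in App-KI and 3.74 ± 0.110 CPM in Trem2-KO at 9 months. The knockout level was 21.6% of the App-KI level at 3 months and 7.10% at 9 months. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Trem2 fell by 2.21 ± 0.13 on the log2 scale at 3 months (adjusted p = 2.84e-09) and fell by 3.81 ± 0.11 at 9 months (adjusted p = 4.12e-15). Counts cover the whole gene and the labels do not say which part was deleted, so the remaining reads do not show whether protein was made. App, the knock-in gene, stood at 1202 ± 12.5 CPM in App-KI and 1226 ± 41.9 CPM in Trem2-KO at 3 months. At 9 months it stood at 1215 ± 15.4 CPM in App-KI and 1190 ± 34.6 CPM in Trem2-KO, and it was called in no comparison by edgeR. The 5 other measured genes of the Trem2 family (Trem1, Trem3, Treml1, Treml2 and Treml4) had too few counts to test, with group means of at most 0.521 CPM, reached by Treml2 in App-KI at 9 months. Among 102 tested genes within 5 Mb of Trem2, 1 was called at each age, Slc35b2, a transporter of the sulfate donor PAPS named at 3 months by the rule and at 9 months after its values were seen. Among 18670 genes farther away or on other chromosomes, 110 were called at 3 months and 393 at 9 months (Fisher's exact test, two-sided, p = 0.455 and 0.727).

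**Figure D1:**
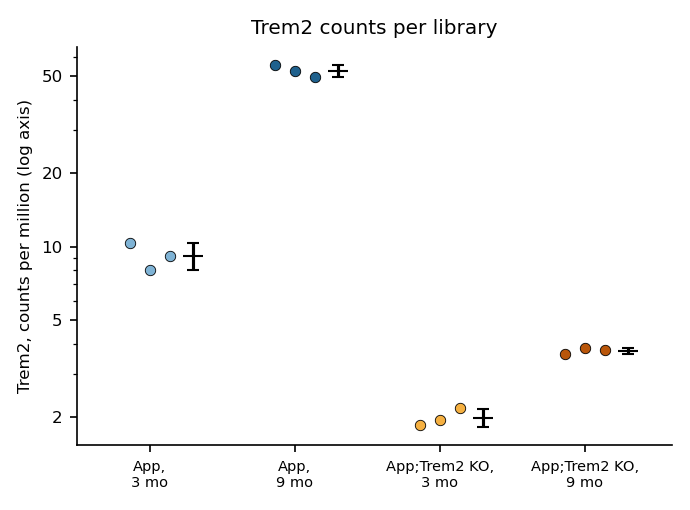
Trem2 CPM on a log axis in each of the 12 libraries (points), with the mean and SD of the 3 libraries per group beside them. App-KI libraries lie between 8.05 and 10.4 CPM at 3 months and between 49.8 and 55.6 CPM at 9 months, and Trem2-KO libraries between 1.85 and 3.83 CPM.

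The comparison of genotypes at 3 months asked how the hippocampus differed without Trem2 at the younger age. Genes of protein folding in the endoplasmic reticulum were lower in Trem2-KO mice: Pdia6, a protein disulfide isomerase, by a log2 fold change of -0.71 ± 0.09, Creld2, a stress-induced folding factor, by -0.79 ± 0.12, Calr, the chaperone calreticulin, by -0.56 ± 0.07, and Hsp90b1, the HSP90 of this compartment, by -0.55 ± 0.10 (3 libraries per group). Derl3, part of the machinery that removes misfolded proteins, fell by 1.60 ± 0.28. Cirbp and Rbm3, RNA-binding proteins induced by mild cold, rose by 0.77 ± 0.08 and 0.52 ± 0.07. Of the 22 measured genes of the unfolded protein and heat shock list, 6 fell and none rose by edgeR over all genes, 16 fell when adjusted over the list alone, and all 22 had a negative value. The list median was -0.45. The list stood below other genes by camera with the preset correlation (adjusted p = 2.25e-25), and had an adjusted p = 0.197 with an estimated correlation. Xbp1, a transcription factor of the same response, fell by 0.48 ± 0.07, while the abundant members Hsp90aa1 (-0.15 ± 0.08), Hspa5 (-0.90 ± 0.17) and Hsph1 (-0.34 ± 0.11) were not called. In all, edgeR's quasi-likelihood test called 113 of 19152 genes, 32 higher and 81 lower, with a median size of 0.37.

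Outside that list, the lower genes included Amd2 (-2.84 ± 0.20), an S-adenosylmethionine decarboxylase copy whose reads may be divided with Amd1, Dna2 (-1.58 ± 0.28), a DNA repair nuclease, Pglyrp1 (-0.95 ± 0.20), a bacterial cell wall binding protein, Adam8 (-0.94 ± 0.18), a membrane protease of immune cells, Dok3 (-0.70 ± 0.13), an adaptor of immune receptors, and Inhba (-0.64 ± 0.12), the activin A subunit. The higher genes were led by H2-Q6 (2.72 ± 0.44), a class I histocompatibility gene that shares sequence with its neighbours and is therefore uncertain. They also held the microRNA host genes Mir9-3hg (0.65 ± 0.11) and Mir22hg (0.54 ± 0.07), Armcx5 (0.50 ± 0.07), Tipin (0.46 ± 0.10), a replication fork protein, Slc9a5 (0.41 ± 0.08), a sodium-proton exchanger, Lias (0.40 ± 0.07), the lipoic acid synthase, Hnrnpdl (0.39 ± 0.07), an RNA-binding protein, Eif2b3 (0.37 ± 0.08), a translation initiation factor, and Slc35b2 (0.36 ± 0.08). Over these 24 genes the adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran up to 0.0387.

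Microglial lists had medians near 0 at this age, with small shifts in the scores per library. Pan-microglial scores were 3.773 to 3.817 in Trem2-KO and 3.90 to 3.93 in App-KI mice, without overlap. Homeostatic scores did not overlap either (4.236 to 4.292 against 4.309 to 4.405), while those of the DAM lists did. No gene of the 22 pan-microglial genes was called by edgeR, 6 had an unadjusted p under 0.05, 3 were lower when adjusted over the list alone, and DESeq2 called 0. Their median was -0.10, with a camera adjusted p = 0.00834 at the preset and adjusted p = 0.355 with an estimated correlation. Of 28 TREM2-dependent genes of disease-associated microglia (DAM), edgeR called 0, 4 had an unadjusted p under 0.05, 2 were higher when adjusted over the list alone and DESeq2 called 1. Their median of -0.05 and mean of -0.16 were negative where camera pointed up (adjusted p = 0.939). Lpl, a lipoprotein lipase, had a value of 0.31 ± 0.08 and Gpnmb, a lysosomal glycoprotein, 0.54 ± 0.16. The 14 complement genes had a median of -0.19 with 0 called by edgeR, 5 with an unadjusted p under 0.05, 3 lower when adjusted over the list alone and 0 by DESeq2. Camera gave an adjusted p = 0.000648, and adjusted p = 0.197 with an estimated correlation. Without Trem2-KO 3-month replicates 1, 2 and 3 in turn this median was -0.34, -0.12 and -0.12. Among immediate early genes, which neurons switch on with activity, Dusp5 fell by 0.34 ± 0.07 as the single call among 22, with 4 lower when adjusted over the list alone. The median was -0.14, with adjusted p = 0.000181 by camera and adjusted p = 0.766 with an estimated correlation. The lysosomal enzyme gene Hexa fell by 0.30 ± 0.07, the glutamine synthetase gene Glul of astrocytes by 0.27 ± 0.06 and the endothelial receptor gene Flt1 by 0.25 ± 0.06, each the single call of its list. Choroid plexus markers had a median of 0.34 in the same direction in all 17 genes, with 0 called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2. Camera gave an adjusted p = 0.0208, and adjusted p = 0.81 with an estimated correlation. That call was lost without App-KI 3-month replicate 1 (-0.14) or 3 (0.07) and Trem2-KO 3-month replicate 2 (0.03), and the median was 1.64 without App-KI 3-month replicate 2.

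The number of genes called at 3 months depended on single libraries: 75 (19 higher, 56 lower), 33 (7 and 26) and 53 (12 and 41) without App-KI replicates 1, 2 and 3, and 54 (18 and 36), 31 (8 and 23) and 26 (10 and 16) without Trem2-KO replicates 1, 2 and 3. Cirbp, Rbm3, Mir22hg, Armcx5, Amd2, Trem2, Pdia6 and Calr were the 8 of the 24 named genes called without each of the 12 libraries in turn.

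The comparison of genotypes at 9 months asked how the response to established amyloid differed without Trem2. Microglial genes were far lower in Trem2-KO mice: Itgax, an integrin of plaque-associated microglia, by -4.31 ± 0.29, Cst7, a cysteine protease inhibitor, by -4.05 ± 0.24, Clec7a, the β-glucan receptor dectin, by -2.91 ± 0.21, and Ccl6, a chemokine, by -1.96 ± 0.12 on the log2 scale (3 libraries per group). Tyrobp, the signalling partner of Trem2, fell by 1.38 ± 0.13, and Ptprc, the leukocyte phosphatase CD45, by 1.44 ± 0.14. The receptors Tlr2 (-1.50 ± 0.18) and Cd14 (-1.35 ± 0.15), the metal transporter Slc11a1 (-1.71 ± 0.15), the adaptor Samsn1 (-1.38 ± 0.16) and Amd2 (-1.95 ± 0.21) were lower too. Genes found in meninges and vessels were higher, among them Slc6a20a (1.30 ± 0.22), a proline transporter, Aebp1 (1.04 ± 0.19), a collagen-binding protein, and Gpr182 (1.10 ± 0.20), an endothelial chemokine-binding receptor. In all, 398 of 19152 genes were called by edgeR's quasi-likelihood test, 131 higher and 267 lower, with a median size of 0.58. With no filter on low counts the balance turned to 437 higher and 394 lower. With the meningeal fibroblast score per library as a covariate, an alternative chosen after seeing the data, 7 genes were called, 0 higher and 7 lower, with 1236 at an unadjusted p under 0.05; the median standard error rose from 0.123 to 0.268, since that score is higher in every Trem2-KO library at 9 months than in the others.

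Of the 22 pan-microglial genes 19 fell, 22 when adjusted over the list alone. The median of these genes was -0.80, and the genes with strong tests included C1qc (-0.87 ± 0.06), a complement subunit, Ctss (-0.96 ± 0.07), a cathepsin, and Laptm5 (-0.83 ± 0.06). Camera gave an adjusted p = 2.29e-57, and adjusted p = 4.12e-05 with an estimated correlation. Arhgdib (-0.28 ± 0.12), Aif1 (-0.47 ± 0.15) and Spi1 (-0.74 ± 0.21) were the members not called. The DAM TREM2-dependent list had 12 lower and 1 higher gene of 28, with 19 lower and 1 higher when adjusted over the list alone and a median of -0.43 (camera adjusted p = 3.2e-25). Cd68, a lysosomal membrane protein of phagocytes, fell by 1.13 ± 0.10. The DAM stage 1 list, whose induction was described as independent of TREM2, had 4 lower of 9, also 4 when adjusted over the list alone. Members had a median of -0.26 (camera adjusted p = 4.62e-10). The called genes were Tyrobp, Lyz2 (-0.87 ± 0.09), the lysozyme of myeloid cells, and the cathepsins Ctsb (-0.26 ± 0.05) and Ctsd (-0.91 ± 0.13), while Apoe, a lipid carrier, had a value of -0.11 ± 0.05 and was not called. Of 18 homeostatic microglial genes 13 fell, 16 when adjusted over the list alone. As a set their median was -0.51 (camera adjusted p = 4.61e-25). Among those called were the fractalkine receptor Cx3cr1 (-0.70 ± 0.07), Selplg (-0.69 ± 0.07), Fcrls (-0.57 ± 0.07) and Gpr34 (-0.65 ± 0.09). Tmem119 was not called (-0.18 ± 0.07). These 3 list calls stood by camera with an estimated correlation (adjusted p = 4.12e-05, 0.00307 and 0.0139). With the meningeal score as a covariate these lists and the pan-microglial list stayed called lower by camera at the preset correlation.

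**Figure D2:**
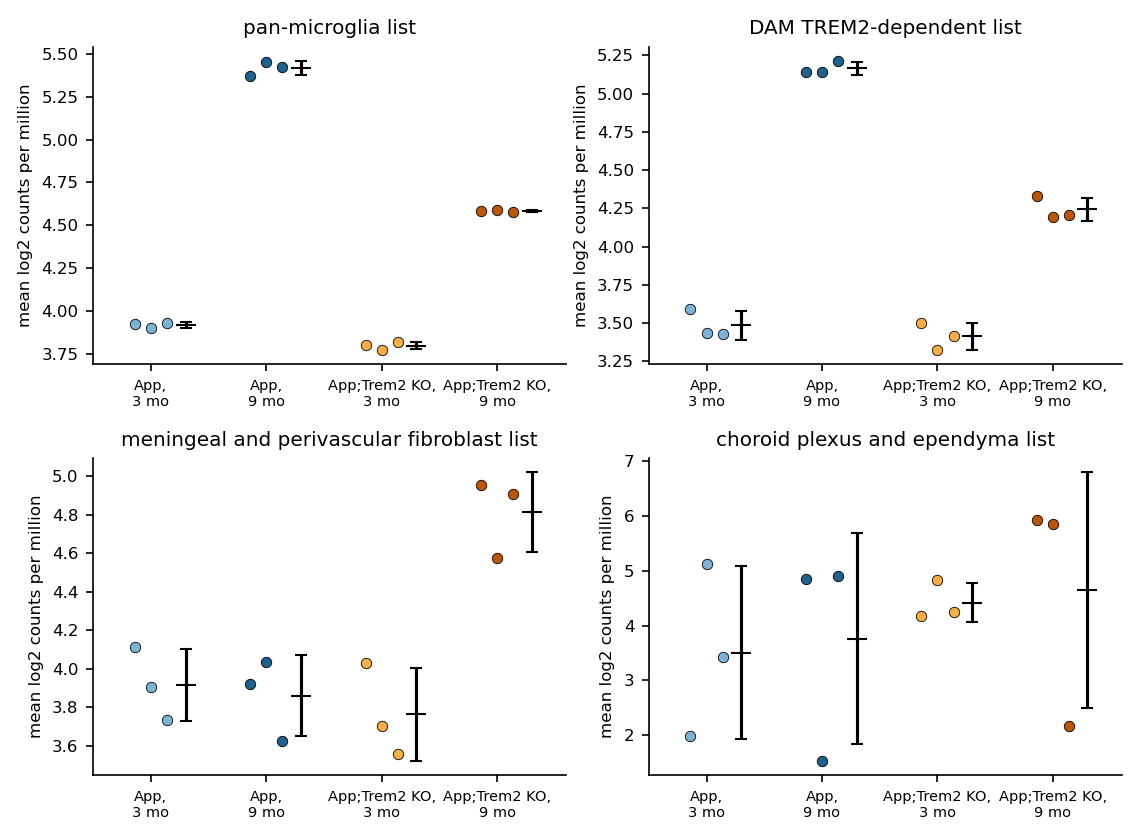
Mean log2 CPM of the members of 4 gene lists in each library (points), with the mean and SD of the 3 libraries per group beside them. The pan-microglial mean is 3.92 and 5.42 in App-KI at 3 and 9 months and 3.80 and 4.58 in Trem2-KO, the meningeal fibroblast mean is 4.81 in Trem2-KO at 9 months and at most 3.92 elsewhere, and choroid plexus means vary within groups.

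Among 14 complement genes, C1qa (-0.85 ± 0.07), C1qb (-0.73 ± 0.07), C1qc and the complement receptor integrin Itgb2 (-1.02 ± 0.11) were among 6 that fell, while 2 rose; 7 fell and 3 rose when adjusted over the list alone. The list's median was -0.36 (camera adjusted p = 1.08e-05, and adjusted p = 0.0294 with an estimated correlation). Of 34 lysosomal genes 13 fell, 17 when adjusted over the list alone. The list had a median of -0.19 and a camera adjusted p = 2.08e-20, against adjusted p = 0.0509 with an estimated correlation. Without Trem2-KO 9-month replicate 3 the median was -0.10. Class II antigen presentation genes had a median of -0.55, with 0 called of 7 by edgeR, 5 at an unadjusted p under 0.05, 5 lower when adjusted over the list alone and 2 by DESeq2. Cd74, the invariant chain, had a value of -1.46 ± 0.37. Camera gave this list an adjusted p = 1.08e-05, and adjusted p = 0.0509 with an estimated correlation, and its median was -0.34 without App-KI 9-month replicate 2. Of 26 reactive astrocyte genes 4 fell, namely Gfap (-0.39 ± 0.05), the astrocyte filament protein, Serpina3n (-0.30 ± 0.07), a protease inhibitor, Cd14 and Ctsb, and 3 rose; 5 fell and 3 rose when adjusted over the list alone. The list's median of -0.05 and its mean of 0.03 differed in sign, and camera pointed down with an adjusted p = 0.35. Among 13 plaque-responsive oligodendrocyte genes Serpina3n and Anxa3 (-0.42 ± 0.08), an annexin, fell, also 2 when adjusted over the list alone. The median was -0.25 with a camera adjusted p = 0.000522, and adjusted p = 0.0509 with an estimated correlation. That median was -0.14 without App-KI 9-month replicate 2 and -0.15 without Trem2-KO 9-month replicate 3. Of 12 oligodendrocyte precursor genes the receptor Gpr17 (-0.52 ± 0.09) and the transcription factors Olig2 (-0.46 ± 0.08) and Olig1 (-0.28 ± 0.07) fell; 5 were lower and 1 higher when adjusted over the list alone. The median stood at -0.17 with a camera adjusted p = 0.00155, and adjusted p = 0.121 with an estimated correlation. Of 32 Alzheimer's disease risk genes, the phosphatase Inpp5d (-0.69 ± 0.08) and the lysosomal protein progranulin, Grn (-0.52 ± 0.06), fell, with 5 lower when adjusted over the list alone, a median of -0.08, a camera adjusted p = 0.00096, and adjusted p = 0.0397 with an estimated correlation.

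Chaperone genes were again lower at 9 months, with 5 called lower of the 22 in the unfolded protein and heat shock list and 12 lower when adjusted over the list alone: Calr (-0.47 ± 0.07), Hspa8 (-0.34 ± 0.06), the constitutive HSP70, Pdia6 (-0.63 ± 0.09) and Hsp90b1 (-0.45 ± 0.10) had the strongest tests. The median was -0.42, with 20 of 22 values negative, a camera adjusted p = 1.49e-12, and adjusted p = 0.121 with an estimated correlation. Without App-KI 9-month replicate 3 the median was -0.26. It was -0.088, and the list no longer called, with the meningeal score as a covariate. Across the genotype comparisons at both ages, which share no library, 45 genes were called in both, 9 higher and 36 lower with 0 in opposite directions, where unrelated lists would share 0.219 and 1.13 (Fisher's exact test, two-sided, p = 6.09e-13 and 1.04e-45). Both comparisons use the same estimate of spread per gene, and genes are not independent replicates, so these p-values overstate the evidence. Cirbp (0.77 ± 0.08) and Rbm3 (0.48 ± 0.07) were among the genes higher at both ages, with these values at 9 months.

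**Figure D3:**
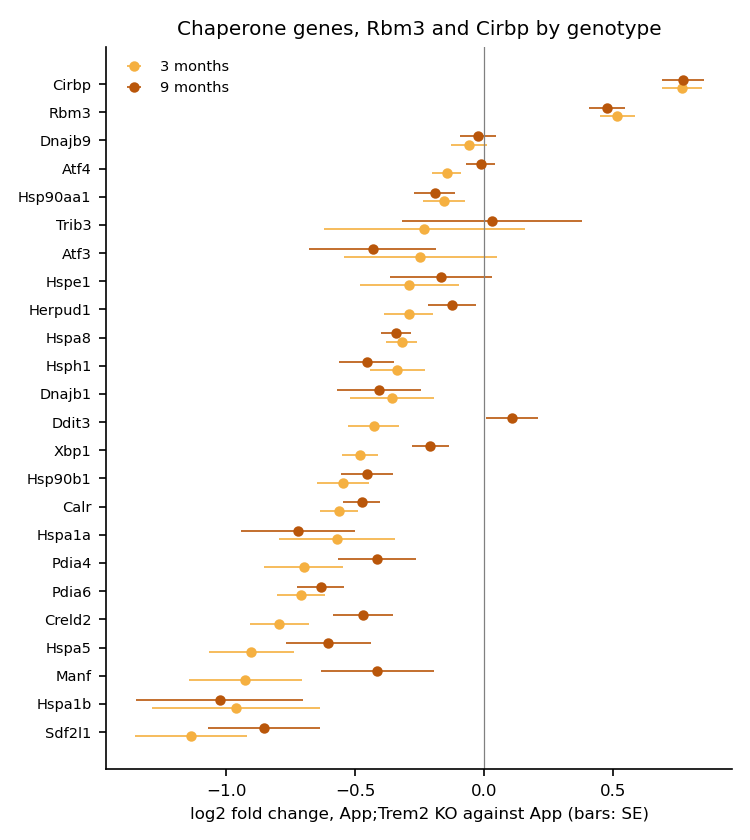
Log2 fold change of Trem2-KO against App-KI, with its standard error, for the 22 genes of the unfolded protein and heat shock list and for Rbm3 and Cirbp at 3 and 9 months (3 libraries per group). All 22 list genes lie below 0 at 3 months and 20 at 9 months, and Rbm3 and Cirbp lie above 0 at both ages.

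Vascular and meningeal markers were higher in Trem2-KO mice at 9 months. Of 14 endothelial genes 3 rose, 7 when adjusted over the list alone, and all 14 values were positive. Together they had a median of 0.24. Kdr, the main VEGF receptor, rose by 0.52 ± 0.09, Itm2a by 0.48 ± 0.07 and the organic anion transporter Slco1a4 by 0.42 ± 0.08. Camera gave an adjusted p = 1.38e-07, and adjusted p = 0.0509 with an estimated correlation. Of 12 meningeal and perivascular fibroblast genes edgeR called 0, 9 had an unadjusted p under 0.05, 9 were higher when adjusted over the list alone and DESeq2 called 5. The median was 1.08 (camera adjusted p = 1.35e-10, and adjusted p = 0.0294 with an estimated correlation), with Col1a2, a collagen chain, at 1.29 ± 0.29. Among 9 measured genes of border macrophages and monocytes the lectin Clec10a rose by 1.94 ± 0.51, 7 were higher when adjusted over the list alone and the median was 0.91, with a camera adjusted p = 1.91e-06, and adjusted p = 0.121 with an estimated correlation. Of 12 mural cell genes Pdgfrb, the pericyte growth factor receptor, rose by 0.33 ± 0.08, also the single call when adjusted over the list alone. The median was 0.22, with a camera adjusted p = 0.0339, and adjusted p = 0.33 with an estimated correlation. The mural call was lost without App-KI 9-month replicate 3 (0.17) or Trem2-KO 9-month replicate 3 (0.24). Choroid plexus markers pointed the same way, with 17 of 17 values positive and a median of 1.004, but edgeR called 0, 0 had an unadjusted p under 0.05 and DESeq2 called 0. Camera gave an adjusted p = 0.00902, and adjusted p = 0.646 with an estimated correlation. Their call was lost without App-KI 9-month replicate 2 (0.52), Trem2-KO 9-month replicate 1 (0.61) or replicate 2 (0.66), and their median was 1.55 without Trem2-KO 9-month replicate 3. The other named higher genes were Aox3 (1.41 ± 0.21), an aldehyde oxidase, Gbp4 (1.32 ± 0.29), an interferon-induced GTPase, Slc26a7 (1.31 ± 0.29), an anion exchanger, Sdc1 (1.22 ± 0.25), a heparan sulfate proteoglycan, Gstm2 (1.14 ± 0.21), a glutathione transferase, Plac9a (1.12 ± 0.28), Alx4 (1.10 ± 0.27), a homeobox factor, Casp12 (1.09 ± 0.23), a caspase, and Ano2 (1.07 ± 0.24), a chloride channel. With the meningeal score as a covariate Slc26a7 (-0.357), Plac9a (-0.402) and Alx4 (-0.209) turned negative and were not called, and so did the medians of the endothelial (-0.077), meningeal fibroblast (-0.279) and border macrophage (-0.485) lists. The meningeal fibroblast genes make up that score, so the loss in their own list was fixed by construction. The mural list turned to -0.386, called lower (adjusted p = 0.0134).

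The number of genes called at 9 months was 241 (60 higher, 181 lower) without App-KI replicate 1, 175 (32 and 143) without App-KI replicate 3 and 213 (53 and 160) without Trem2-KO replicate 1. Without Trem2-KO replicate 3 it was 556, with 271 higher and 285 lower, so the balance of directions depended on single libraries. Of the 24 named genes 15 were called without each of the 12 libraries in turn: Aox3, Gstm2, Gpr182, Itgax, Cst7, Trem2, Clec7a, Ccl6, Amd2, Slc11a1, Tlr2, Ptprc, Tyrobp, Samsn1 and Cd14.

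The comparison of ages in App-KI mice asked what changed from 3 to 9 months while amyloid accumulated with Trem2 present. Microglial genes rose most: Cst7 by 6.55 ± 0.31, Clec7a by 5.76 ± 0.28 and Itgax by 5.71 ± 0.34 on the log2 scale, from 3-month means of 0.432, 0.377 and 0.252 CPM, followed by the chemokine Ccl6 (3.58 ± 0.14), lysozyme Lyz2 (2.76 ± 0.10) and Slc11a1 (2.58 ± 0.16). Class II antigen presentation genes rose with them, with Cd74 up by 3.70 ± 0.42, H2-Aa by 3.48 ± 0.44, H2-Ab1 by 3.25 ± 0.35 and H2-Eb1 by 2.81 ± 0.26. C4b, a complement component whose reads may be divided with C4a, rose by 2.87 ± 0.18, and H2-Q6 by 2.73 ± 0.44. The lower genes changed less and included Opalin (-0.81 ± 0.16), a myelin sialoglycoprotein, Cck (-0.77 ± 0.17), a neuropeptide, and Tacr3 (-0.76 ± 0.17), a neurokinin receptor. In all, edgeR's quasi-likelihood test called 1276 genes, 757 higher and 519 lower, with a median size of 0.52.

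All 22 pan-microglial genes rose. Their median was 1.53 (camera with an estimated correlation, adjusted p = 1.49e-05). Ctss rose by 2.08 ± 0.07, C1qc by 1.61 ± 0.06 and Laptm5 by 1.72 ± 0.07. Of 28 DAM TREM2-dependent genes 21 rose, 24 when adjusted over the list alone, and 1 fell. The list median was 0.87 (estimated correlation, adjusted p = 1.49e-05). Ctsz, a cathepsin, rose by 1.67 ± 0.07 and Cd68 by 2.17 ± 0.10. DAM stage 1 genes rose in 7 of 9 cases, 8 higher and 1 lower when adjusted over the list alone. The median of these genes was 0.95 (estimated correlation, adjusted p = 0.000296). The called genes included Tyrobp (2.09 ± 0.14), Ctsd (1.69 ± 0.14) and Ctsb (0.50 ± 0.05). Homeostatic microglial genes rose in 16 of 18 cases, 17 when adjusted over the list alone. Members had a median of 0.76 (estimated correlation, adjusted p = 0.00272). Called members included Fcrls (1.23 ± 0.07), Selplg (1.02 ± 0.07), Olfml3 (1.11 ± 0.09) and Siglech (1.11 ± 0.09). Of 14 complement genes 10 rose, 11 when adjusted over the list alone. As a set their median was 1.358 (estimated correlation, adjusted p = 0.000272). The class I presentation list had 11 of 13 higher, 12 when adjusted over the list alone. The list had a median of 1.14 (estimated correlation, adjusted p = 0.0244). Among those called were Psmb8, an immunoproteasome subunit (1.48 ± 0.22), and Tap2, a peptide transporter (0.74 ± 0.12). Class II genes rose in 6 of 7 cases, 6 when adjusted over the list alone. The median stood at 2.81 (estimated correlation, adjusted p = 0.00785). Lysosomal genes rose in 23 of 34 cases, 30 when adjusted over the list alone. Together they had a median of 0.47 (estimated correlation, adjusted p = 0.00736).

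The reactive astrocyte and plaque-responsive oligodendrocyte lists rose as well. Of the 13 genes of the oligodendrocyte list 7 are in another list, and whole-tissue counts do not show which cells changed. Gfap rose by 1.98 ± 0.05 and Osmr, the oncostatin M receptor, by 1.61 ± 0.12, among 11 higher of 26 reactive astrocyte genes and 13 when adjusted over the list alone (median 0.45, camera with an estimated correlation, adjusted p = 0.000904). Of 13 plaque-responsive oligodendrocyte genes 10 rose, also 10 when adjusted over the list alone. Their median was 0.94 (estimated correlation, adjusted p = 0.000296). The called genes included C4b, Serpina3n (0.70 ± 0.07), Anxa3 (0.94 ± 0.08) and the tetraspanin Cd9 (0.92 ± 0.10). Of 32 risk genes for Alzheimer's disease 11 rose, with 11 higher and 1 lower when adjusted over the list alone and a median of 0.10 (estimated correlation, adjusted p = 0.00272): Inpp5d rose by 1.37 ± 0.08, Grn by 0.99 ± 0.06, Plcg2, a phospholipase, by 1.05 ± 0.12 and Apoe by 0.36 ± 0.05. The lipid handling list had 10 higher and 2 lower of 23, 12 and 2 when adjusted over the list alone. The list median was 0.35 (estimated correlation, adjusted p = 0.015). Ch25h, a cholesterol hydroxylase, rose by 2.18 ± 0.36. Of 25 interferon response genes 5 rose, 7 when adjusted over the list alone. The median of these genes was 0.41 with a camera adjusted p = 5.33e-06, and adjusted p = 0.347 with an estimated correlation. The sensor gene Ifi204 rose by 2.30 ± 0.39 and Trim30a by 1.18 ± 0.22, and the median was 0.21 without App-KI 9-month replicate 2.

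The other named lower genes were Smim18 (-1.20 ± 0.21), Btbd16 (-1.06 ± 0.28), Ndufa4l2 (-1.05 ± 0.31), Malat1 (-0.88 ± 0.14), a nuclear long noncoding RNA, Igfbp6 (-0.86 ± 0.21), a binding protein of insulin-like growth factors, Flywch2 (-0.85 ± 0.25), Hist3h2ba (-0.81 ± 0.14), a histone, Grem1 (-0.80 ± 0.20), a BMP antagonist, and Timm10 (-0.80 ± 0.20), a mitochondrial import chaperone. The number of genes called was 811 (522 higher, 289 lower) without App-KI 3-month replicate 3, 794 (527 and 267) without App-KI 9-month replicate 1, 788 (543 and 245) without App-KI 9-month replicate 2, and 826 without the 3 libraries with the lowest choroid plexus markers, an alternative chosen after seeing the data. Of the 24 named genes 16 were called without each of the 12 libraries in turn. Btbd16, Ndufa4l2, Igfbp6, Flywch2, Grem1, Timm10, Cck and Tacr3 were not.

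The comparison of ages in Trem2-KO mice asked which of these changes took place without Trem2. Clec7a rose by 4.28 ± 0.41, Cst7 by 2.79 ± 0.41 and Itgax by 2.73 ± 0.61. Their means in Trem2-KO mice at 3 months were 0.153, 0.358 and 0.106 CPM, for Clec7a and Itgax within or below the 0.122 to 0.205 CPM of 3 counts in a library, so the sizes of these changes rest on few counts. Complement genes rose, with C4b up by 3.05 ± 0.19 and C3, the central complement protein, by 2.47 ± 0.40, and so did the antigen presentation genes H2-Ab1 (2.39 ± 0.37), Cd74 (2.19 ± 0.43) and H2-Aa (2.14 ± 0.45). Lyz2 rose by 2.20 ± 0.10 and Aspg, an asparaginase of reactive astrocytes, by 2.15 ± 0.24. In all, edgeR's quasi-likelihood test called 1667 genes, 1088 higher and 579 lower, with a median size of 0.47. Adding the meningeal score as a covariate left 25 calls, 23 higher and 2 lower, as the median standard error rose from 0.123 to 0.292.

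Of 22 pan-microglial genes 20 rose, 21 when adjusted over the list alone. Members had a median of 0.82 (camera with an estimated correlation, adjusted p = 0.000445). Called members included Ctss (1.15 ± 0.07), Mpeg1 (1.72 ± 0.11), a pore-forming protein of phagocytes, and Laptm5 (0.99 ± 0.07). Aif1 (0.04 ± 0.15) and Spi1 (0.47 ± 0.22) were not called. Of 28 DAM TREM2-dependent genes 16 rose and 1 fell, 18 and 2 when adjusted over the list alone. As a set their median was 0.65 (estimated correlation, adjusted p = 0.000738). DAM stage 1 genes rose in 6 of 9 cases, 7 when adjusted over the list alone. The list had a median of 0.39 (estimated correlation, adjusted p = 0.00176). Among those called were Tyrobp (1.06 ± 0.15) and Apoe (0.30 ± 0.05). Homeostatic genes rose in 13 of 18 cases, 14 when adjusted over the list alone. The median stood at 0.49 (estimated correlation, adjusted p = 0.0298). The called genes included Fcrls (0.83 ± 0.07) and Tmem119 (0.52 ± 0.07). Of 14 complement genes 13 rose, also 13 when adjusted over the list alone. Together they had a median of 1.21 (estimated correlation, adjusted p = 0.000445). Class II genes rose in 5 of 7 cases, also 5 when adjusted over the list alone. Their median was 1.71 (estimated correlation, adjusted p = 0.0377). It was 0.408 and no longer called with the meningeal score as a covariate. For class I genes 8 of 13 rose, 12 when adjusted over the list alone. The list median was 0.85 with a camera adjusted p = 3.91e-09, and adjusted p = 0.0569 with an estimated correlation. It too was no longer called with the meningeal score (0.317). Gfap rose by 1.63 ± 0.05, among 15 higher of 26 reactive astrocyte genes and 18 when adjusted over the list alone (median 0.41, estimated correlation, adjusted p = 0.00115), and 8 of 13 plaque-responsive oligodendrocyte genes rose, 11 when adjusted over the list alone (median 0.54, estimated correlation, adjusted p = 0.00165). Lysosomal genes rose in 23 of 34 cases, 27 when adjusted over the list alone (median 0.34, estimated correlation, adjusted p = 0.0345), and lipid handling genes in 11 of 23, with 2 lower, and 11 and 3 when adjusted over the list alone (median 0.35, estimated correlation, adjusted p = 0.0345). Of 32 risk genes 6 rose, 14 when adjusted over the list alone (median 0.19, estimated correlation, adjusted p = 0.0112). Interferon response genes had 7 higher of 25, 12 when adjusted over the list alone. The median of these genes was 0.64 with a camera adjusted p = 3.42e-11, and adjusted p = 0.135 with an estimated correlation. Without Trem2-KO 3-month replicate 2 the median was 0.43.

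Vascular and meningeal genes also rose from 3 to 9 months in Trem2-KO mice. Of 14 endothelial genes 6 rose, 9 when adjusted over the list alone. Members had a median of 0.28 (camera with an estimated correlation, adjusted p = 0.0345). Called members included Kdr (0.70 ± 0.09), Flt1 (0.33 ± 0.06), the glucose transporter Slc2a1 (0.29 ± 0.06) and the cadherin Cdh5 (0.61 ± 0.14). Of 12 meningeal fibroblast genes 6 rose, 7 when adjusted over the list alone. As a set their median was 1.03 (estimated correlation, adjusted p = 0.0283). Among those called were Ogn, a matrix proteoglycan (1.53 ± 0.27), Aldh1a2, a retinoic acid synthesis enzyme (1.86 ± 0.36), and the growth factor Igf2 (1.17 ± 0.30). Border macrophage genes rose in 3 of 9 cases, 7 when adjusted over the list alone. The list had a median of 0.98 with a camera adjusted p = 7.48e-06, and adjusted p = 0.11 with an estimated correlation. Mural genes rose in 3 of 12 cases, 6 when adjusted over the list alone. The median stood at 0.42 with a camera adjusted p = 5.77e-05, and adjusted p = 0.0569 with an estimated correlation. Cdh1, an epithelial cadherin, rose by 2.23 ± 0.55 and Slc6a12, a betaine transporter, by 2.09 ± 0.51. Under the meningeal covariate both turned negative and were not called (-0.971 and -0.324), and so did the medians of the meningeal fibroblast (-0.091), border macrophage (-0.29) and mural lists (-0.169), while the endothelial median was 0.045. None of these 4 lists was called with that covariate, which is the mean of the meningeal fibroblast genes themselves. The lower genes were led by Top2a (-1.26 ± 0.27), a topoisomerase of dividing cells, and held Dctpp1 (-1.02 ± 0.19), a nucleotide hydrolase, Smim18 (-0.95 ± 0.20), Fgf16 (-0.92 ± 0.24), a growth factor, Fst (-0.91 ± 0.24), the activin antagonist follistatin, Fxyd7 (-0.89 ± 0.17), a sodium pump regulator, Pgam2 (-0.81 ± 0.15), a glycolytic mutase, Gamt (-0.79 ± 0.11), a creatine synthesis enzyme, Tnc (-0.79 ± 0.17), the matrix protein tenascin, Serf1 (-0.78 ± 0.18), Cbx8 (-0.76 ± 0.12), a Polycomb protein, and Rnf122 (-0.76 ± 0.12).

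The age comparisons of the genotypes share no library but use the same estimate of spread per gene. Of the genes called in both, 439 rose in both and 232 fell in both, where unrelated lists would share 43.0 and 15.7, and 1 went in opposite directions (Gm42047, named after its values were seen). Across genes, which are not independent replicates, the changes with age in App-KI and Trem2-KO mice had a Pearson correlation of 0.50, and over the genes called in App-KI mice 97.3% had the same sign in Trem2-KO mice with a slope of 0.56. Choosing genes by their App-KI values lowers that slope even where true changes are equal, so it does not measure a weaker response. The number of genes called in Trem2-KO mice was 1042 (707 higher, 335 lower) without Trem2-KO 3-month replicate 2, 769 (583 and 186) without Trem2-KO 3-month replicate 3 and 932 (704 and 228) without Trem2-KO 9-month replicate 2. Of the 24 named genes 16 were called without each of the 12 libraries in turn. Itgax, Cdh1, Cd74, H2-Aa, Slc6a12, Fgf16, Fst and Serf1 were not.

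**Figure D4:**
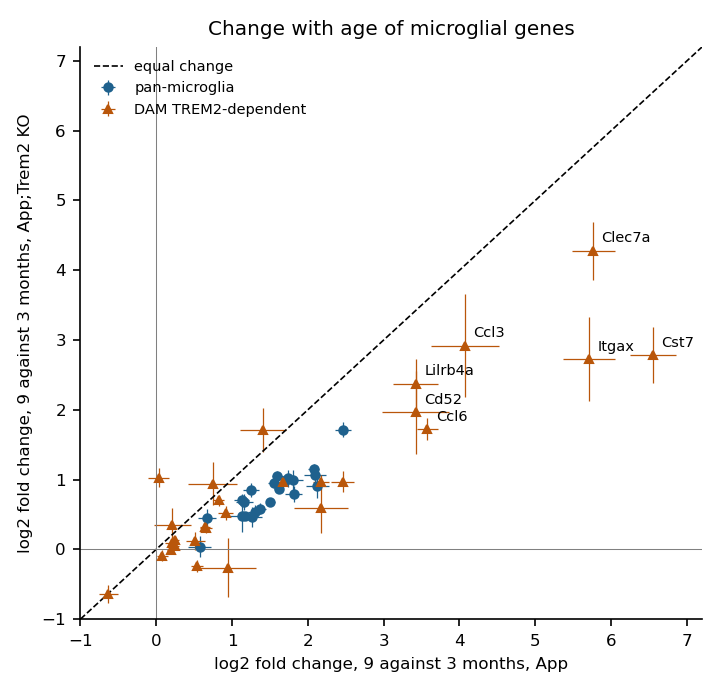
Log2 fold change from 3 to 9 months in App-KI mice (horizontal) and in Trem2-KO mice (vertical), with standard errors, for pan-microglial and DAM TREM2-dependent genes; the dashed line marks equal change. Cst7 rose by 6.55 in App-KI and 2.79 in Trem2-KO mice, Clec7a by 5.76 and 4.28, and Ccl6 by 3.58 and 1.73.

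The interaction of age and genotype asked which genes changed differently with age in Trem2-KO and in App-KI mice, and its values are the change in Trem2-KO minus that in App-KI. Microglial genes rose less in Trem2-KO mice: Cst7 by -3.77 ± 0.67, Ccl6 by -1.85 ± 0.21, Cd14 by -1.62 ± 0.24, Gpnmb by -1.49 ± 0.21 and Cd68 by -1.20 ± 0.15. Trem2 itself had -1.61 ± 0.17. The other named lower genes were Samsn1 (-1.76 ± 0.24), Slc11a1 (-1.37 ± 0.24), Klhl6 (-1.37 ± 0.27), Ptprc (-1.22 ± 0.22), Hcls1 (-1.15 ± 0.24) and Myo1f (-1.06 ± 0.20). The higher genes included Kdr (0.82 ± 0.13), Gpr182 (1.59 ± 0.28), Klf2 (0.85 ± 0.16), a flow-responsive transcription factor, Osr1 (1.42 ± 0.28), a mesenchymal transcription factor, and the matrix genes Ecm1 (0.98 ± 0.19) and Fbln1 (0.75 ± 0.15). In all, 51 genes were called by edgeR's quasi-likelihood test, 11 higher and 40 lower, with a median size of 0.83. The balance depended on the method: DESeq2 called 44 higher and 58 lower, and edgeR with no filter on low counts 113 higher and 74 lower. With that meningeal covariate edgeR called 0, with 830 at an unadjusted p under 0.05, as the median standard error rose from 0.174 to 0.328. DESeq2 was not run with it. The pan-microglial, homeostatic and both DAM lists stayed called lower with it by camera at the preset correlation.

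Of 22 pan-microglial genes 13 were called lower, 21 when adjusted over the list alone. Together they had a median of -0.73 (camera with an estimated correlation, adjusted p = 9.24e-05). Ctss had -0.92 ± 0.10, C1qc -0.75 ± 0.09 and Csf1r, the receptor that keeps microglia alive, -0.69 ± 0.08. The DAM TREM2-dependent list had 6 lower and 1 higher of 28, 13 and 1 when adjusted over the list alone. Their median was -0.40 (estimated correlation, adjusted p = 0.000131). The called genes included Lpl (-0.78 ± 0.11). The DAM stage 1 list had 1 lower of 9, Tyrobp (-1.03 ± 0.20), 6 when adjusted over the list alone. The list median was -0.56 (estimated correlation, adjusted p = 0.00398). Homeostatic genes had 2 lower of 18, Cx3cr1 (-0.57 ± 0.10) and Selplg (-0.53 ± 0.11), 11 when adjusted over the list alone. The median of these genes was -0.38 (estimated correlation, adjusted p = 0.0346). Lysosomal genes had 7 lower of 34, 15 when adjusted over the list alone. Members had a median of -0.18 with a camera adjusted p = 2.72e-21, and adjusted p = 0.0607 with an estimated correlation. Without Trem2-KO 9-month replicate 3 the median was -0.11. Of 14 complement genes C1qa (-0.60 ± 0.11), C1qb (-0.55 ± 0.10), C1qc and Itgb2 (-0.94 ± 0.17) were lower, with 5 lower and 3 higher when adjusted over the list alone. The list's median of 0.09 and mean of 0.05 were positive where camera pointed down (adjusted p = 0.0923). C4b, made by astrocytes and oligodendrocytes among others, had 0.18 ± 0.25 and was not called. Gfap (-0.35 ± 0.07) and Cd14 were lower among 26 reactive astrocyte genes, with 5 lower and 2 higher when adjusted over the list alone and a camera adjusted p = 0.751. Inpp5d (-0.79 ± 0.11) and Grn (-0.50 ± 0.08) were lower among 32 risk genes, also 2 when adjusted over the list alone. As a set their median was -0.03 (camera adjusted p = 0.0527).

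The endothelial list had positive values in the interaction, with Kdr the single gene called of 14, 8 higher when adjusted over the list alone, 14 positive values and a median of 0.30 (camera with an estimated correlation, adjusted p = 0.0248). Of 12 meningeal fibroblast genes edgeR called 0, 7 had an unadjusted p under 0.05, 7 were higher when adjusted over the list alone and DESeq2 called 0. The median was 1.22 (estimated correlation, adjusted p = 0.0248), with Aldh1a2 at 1.79 ± 0.51. Border macrophage genes had 0 called of 9 by edgeR, 8 with an unadjusted p under 0.05, 8 higher when adjusted over the list alone and 1 by DESeq2. The list had a median of 1.22 with a camera adjusted p = 5.77e-10, and adjusted p = 0.0622 with an estimated correlation. The choroid plexus list had a median of 0.63 with 0 of 17 genes called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.859). Under the meningeal covariate the endothelial (-0.046), meningeal fibroblast (-0.255) and border macrophage (-0.356) medians turned negative and were not called. That covariate is the mean of the meningeal fibroblast genes themselves. The other higher genes of the rule were Aox3 (1.503 ± 0.31), Colec12 (0.997 ± 0.20), a scavenger receptor, and Lef1 (0.83 ± 0.17), a Wnt pathway transcription factor. The number of genes called was 32 (3 higher, 29 lower) without App-KI 9-month replicate 3 and 29 (3 and 26) without Trem2-KO 3-month replicate 3. The count of higher genes also moved without App-KI 3-month replicate 3 (17 higher, 40 lower) or 9-month replicate 1 (5 and 34), without Trem2-KO 3-month replicate 2 (5 and 30), and without Trem2-KO 9-month replicate 1 (7 and 35), 2 (29 and 47) or 3 (18 and 40). Kdr, Ccl6, Samsn1, Cd14, Trem2, Gpnmb and Cd68 were the 7 of the 21 named genes called without each of the 12 libraries in turn.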

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

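The tests of a lower share of microglia, of dilution by other tissue and of meningeal tissue behind the chaperone pattern, and the settings with a choroid plexus or meningeal score, were chosen after the results were seen; the other tests were written before. What singled out 51 genes and 6 lists is a difference between the genotypes in the change with age, tested by the interaction term of edgeR's quasi-likelihood model with Benjamini-Hochberg adjustment, or for lists by camera with the preset and with an estimated correlation. The values are changes with age in Trem2-KO minus those in App-KI mice on the log2 scale. List medians were -0.73 for pan-microglial, -0.40 for DAM TREM2-dependent, -0.56 for DAM stage 1 and -0.38 for homeostatic microglial genes, and 0.30 for endothelial and 1.22 for meningeal fibroblast genes. Among genes higher by this measure were Gpr182 (1.59), Aox3 (1.503), Osr1 (1.42), Colec12 (0.997), Ecm1 (0.98), Klf2 (0.85), Lef1 (0.83), Kdr (0.82) and Fbln1 (0.75). Among the lower ones were Cst7 (-3.77), Ccl6 (-1.85), Samsn1 (-1.76), Cd14 (-1.62), Trem2 (-1.61), Gpnmb (-1.49), Slc11a1 (-1.37), Klhl6 (-1.37), Ptprc (-1.22), Cd68 (-1.20), Hcls1 (-1.15) and Myo1f (-1.06). Groups of 3 libraries are too small for a test of single outlying samples.

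The first pattern is that microglial lists were lower in Trem2-KO mice at 9 months. A lower share of microglia alone would lower homeostatic and pan-microglial genes alike if no other cells expressed them. The difference of the 2 scores was -0.27 ± 0.018 (SD, n = 3) in App-KI and 0.11 ± 0.104 in Trem2-KO mice, 5.1 pooled SDs apart. Expression of the homeostatic genes in other cells, which whole tissue does not show, could also give such a gap, so this test does not decide. Dilution by meningeal or choroid plexus tissue would lower astrocyte and neuron genes about as much, but their list medians lay no farther from 0 than -0.074. A weaker activation of microglia without Trem2, the difference the design names, may account for the pattern and stays open as a hypothesis. A lower share of microglia, alone or beside it, stays open too.

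The second pattern, not singled out by the interaction but by its presence at both ages, is that chaperone genes were lower and Cirbp and Rbm3 higher in Trem2-KO mice. No single library carries it, since the list's median stayed at or below -0.263 without each of the 12 libraries, and with the choroid plexus score as a covariate it stayed at or below -0.469 at both ages. With the meningeal score as a covariate the list's median was -0.494 at 3 months. That score was 3.916 ± 0.189 (SD, n = 3) in App-KI and 3.764 ± 0.241 in Trem2-KO mice at 3 months, so the covariate could move the median little. The similar scores, not the covariate fit, argue against meningeal tissue at that age. At 9 months the list's median went from -0.416 to -0.088 with the covariate and the list was no longer called, while the median standard error rose from 0.111 to 0.228. Of that score's variance 85.6% lies between the groups, so at 9 months the covariate fit cannot separate meningeal tissue from genotype. Dilution by such tissue would lower astrocyte and neuron genes about as much, but their medians lay no farther from 0 than -0.074. Chaperone list scores at 9 months were 6.106 to 6.15 in Trem2-KO and 6.331 to 6.737 in App-KI mice, without overlap. These values argue against meningeal tissue for the lower chaperone genes. They do not cover the rise of Cirbp and Rbm3. A different time of day at collection could produce it, but of 20 clock genes edgeR called 0 at 3 months (9 at an unadjusted p under 0.05, 8 when adjusted over the list alone, 4 by DESeq2) and 1 at 9 months (Nr1d1, 0.33 ± 0.07; 9 at an unadjusted p under 0.05, 7 when adjusted over the list alone, 2 by DESeq2), below the 3 per age set in advance. The rotation test fry of limma, for change in either direction across the clock genes, nevertheless gave at most an adjusted p = 0.000969 at either age (Benjamini-Hochberg over the 2 ages). The labels give no collection time, litter or batch, so none of these can be told apart from genotype, which also stays open, untested. In 6 clock genes with an unadjusted p under 0.05 at both ages (Dbp, Per3, Nr1d1, Tef, Hlf and Arntl, listed after their values were seen) the sign was the same at both ages.

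The third pattern is that vascular and meningeal genes were higher in Trem2-KO mice at 9 months. Choroid plexus tissue carried along argues poorly for it, since the meningeal list's median stayed at 1.112 with the choroid plexus score as a covariate. With the meningeal score as a covariate the endothelial median went from 0.24 to -0.077, but the median standard error rose from 0.102 to 0.207 and 85.6% of the variance of that score lies between the groups, so meningeal tissue carried over in dissection cannot be told apart from a change with genotype and age. Both may contribute. The most abundant meningeal genes, Dcn and Igfbp2, had values of 0.47 ± 0.21 and 0.77 ± 0.52 at 9 months, and edgeR called 0 of the list's 12 genes there (9 at an unadjusted p under 0.05, 5 by DESeq2). Of the list's 12 measured genes none is in another list used here.

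Of the 10 ways to split the 6 libraries, the real split gave the most calls in each comparison of 2 groups: 1 of 10 splits reached 113 at 3 months (highest other 0), 1 reached 398 at 9 months (highest other 1), 1 reached 1276 for age in App-KI (highest other 0) and 1 reached 1667 for age in Trem2-KO (highest other 0). With 10 splits the share cannot go under 0.05. For the interaction, 10 of 100 splits of the genotypes within each age gave 51 or more calls. The other 9 of these all keep the 9-month libraries of each genotype together and so carry the genotype effect at that age, and of the 85 splits that mix them none gave more than 2 calls. The count therefore does not decide whether chance can be excluded. The highest other gave 793, from the split that exchanges the genotypes at 1 age and so adds the genotype effects of both ages, which is a structure of the samples.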

How the results depend on the processing

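The choroid plexus score, the meningeal score, the fit without 3 libraries and the fold minimum for the genotype overlap were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each library has its own mouse identifier and the labels give no replicate numbers shared between groups. Trem2 stayed called and lower at both ages in every alternative fit. Of the 352 named gene results, 351 were the same with DESeq2, 352 with DESeq2-type size factors, 334 with library size alone, 347 with no filter, 349 with the stricter filter, 342 with voom weights, 310 with a fit that is not robust (42 weaker), 287 with only the groups compared (29 weaker), 344 with 1 surrogate variable, 346 with the choroid plexus score, 280 without the 3 libraries (72 weaker) and 137 with the meningeal score (203 weaker). Leaving out each library in turn, 3575 were the same and 649 weaker. With an estimated correlation 127 list results were the same and 68 weaker. Depth limits genes with few counts, such as the TREM family, and smaller simulated changes were recovered less often.

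Counts that moved by more than 1.5 times were these, and except where fewer genes or libraries enter by construction the cause was not tested. At 3 months the 113 calls became 261 with DESeq2, 347 with no filter, 218 with only the groups compared, 253 with voom weights, 30 with the fold minimum, 196 with 1 surrogate variable and 180 with the choroid plexus score. At 9 months the 398 became 831 with no filter (437 higher, 394 lower), 225 with the fold minimum and 7 with the meningeal score. The fold minimum left 685 of 1276 and 782 of 1667 age calls, and 306 genes in the age overlap. The meningeal score left 25 age calls in Trem2-KO and 0 in the interaction, where the score is nearly the same as the Trem2-KO group at 9 months. The interaction's 51 became 102 with DESeq2 (44 higher, 58 lower), 187 with no filter (113 higher, 74 lower), 83 with 1 surrogate variable (34 and 49) and 81 with the choroid plexus score (32 and 49). The genotype overlap of 45 became 89 with DESeq2 and 6 with the fold minimum (1 higher, 5 lower). Without the 3 libraries low in choroid plexus markers the 1276 age calls in App-KI became 826. Leaving out 1 library gave 26 to 154 at 3 months, 175 to 556 at 9 months, 788 to 1523 for age in App-KI, 769 to 1920 for age in Trem2-KO and 29 to 76 for the interaction; Trem2 lay between -2.29 and -2.11 at 3 months and between -3.85 and -3.78 at 9 months.

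A value, or for lists the direction of the test, reversed as follows. With 1 surrogate variable, which follows the choroid plexus score, this was the choroid plexus list at 9 months (-0.193), with age in Trem2-KO (-0.308) and in the interaction (-0.304). With the meningeal score, genotype at 9 months reversed for Alx4 (-0.209), Plac9a (-0.402) and Slc26a7 (-0.357) and for the lists of glycolysis (0.121), ribosomal proteins (-0.113), immediate early genes (0.242), myelinating oligodendrocytes (-0.229) and mural cells (-0.386). Age in Trem2-KO reversed with it for Anpep (-0.125), Cd163 (-0.269), Cdh1 (-0.971), F13a1 (-0.29), Mrc1 (-0.669), Pdgfra (-0.061), Slc6a12 (-0.324), Slc6a13 (-0.337), Vtn (-0.214), glycolysis (0.129) and immediate early genes (0.276), and the interaction for glycolysis (0.117) and mural cells (-0.226). Reversals without 1 library were the choroid plexus list in the interaction without App-KI 9-month replicate 2 (0.16; range -0.666 to 1.158), immediate early genes at 9 months without App-KI 9-month replicate 3 (range -0.137 to 0.144), and, without Trem2-KO 9-month replicate 1, ribosomal proteins at 9 months (range -0.077 to 0.132) and nuclear OXPHOS in the interaction (range -0.029 to 0.055). The erythroid interaction was -0.639 without the 3 libraries. The cause was not tested.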

Other observations

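All tests in this part were fixed before the data were examined except where a sentence says otherwise. With age, lists of mitochondrial respiration and of ribosomal proteins were lower in both genotypes, while glycolysis was not. Of 52 nuclear OXPHOS genes 19 fell in App-KI (33 when adjusted over the list alone, median -0.27) and 14 in Trem2-KO mice (34, median -0.32), including the respiratory subunit genes Atp5d (-0.44 ± 0.07 and -0.34 ± 0.07) and Uqcrb (-0.45 ± 0.09 and -0.45 ± 0.09). Camera gave an adjusted p = 1.41e-21 and 8.47e-20, and adjusted p = 0.0527 and 0.0515 with an estimated correlation. Of 12 mitochondrially encoded genes 4 and 2 fell, 5 and 5 when adjusted over the list alone (medians -0.10 and -0.16), among them mt-Nd1 (-0.30 ± 0.05 and -0.25 ± 0.05), with adjusted p = 0.327 and 0.391 with an estimated correlation. The call in Trem2-KO was lost without its 3-month replicate 3 (-0.13) or its 9-month replicate 2 (-0.10). Of 39 ribosomal protein genes 6 and 4 fell, 16 and 16 when adjusted over the list alone (with 2 higher in App-KI), with medians of -0.18 and -0.22 and adjusted p = 0.331 and 0.14 with an estimated correlation. Without Trem2-KO 9-month replicate 2 the second median was -0.12. TCA cycle genes fell in 1 and 3 of 20 cases, 1 and 4 when adjusted over the list alone, with adjusted p = 0.209 and 0.18 with an estimated correlation. Sdhb fell by 0.35 ± 0.06 and 0.25 ± 0.06. In glycolysis 4 of 22 genes rose in App-KI, 5 when adjusted over the list alone: Hk2 (0.67 ± 0.14), Pfkfb3 (0.31 ± 0.07), Slc2a1 (0.27 ± 0.06) and Aldoc (0.22 ± 0.06). The median of -0.02 and mean of 0.07 differed in sign, and camera pointed up with an adjusted p = 0.548. In Trem2-KO mice Slc2a1 (0.29 ± 0.06) and Aldoc (0.21 ± 0.06) rose, also 2 when adjusted over the list alone, with a median of -0.02 and a camera adjusted p = 0.438.

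Some neuronal lists were lower with age. Of 11 excitatory neuron genes 2 fell in App-KI and 4 in Trem2-KO mice, 4 and 7 when adjusted over the list alone, with medians of -0.09 and -0.20 and adjusted p = 0.0527 and 0.0242 with an estimated correlation. Nrgn, a calmodulin-binding postsynaptic protein, fell by 0.48 ± 0.06 and fell by 0.40 ± 0.06, and the first median was -0.04 without App-KI 3-month replicate 3. Of 17 inhibitory neuron genes 3 fell in each, 4 and 5 when adjusted over the list alone, such as the neuropeptides Npy (-0.47 ± 0.12 and -0.49 ± 0.12) and Vip (-0.39 ± 0.11 and -0.41 ± 0.11), with adjusted p = 0.167 and 0.172 with an estimated correlation and medians of -0.09 and -0.08. The first of these was -0.03 without App-KI 3-month replicate 1 and -0.15 without App-KI 9-month replicate 3, the second -0.14 and -0.13 without Trem2-KO 3-month replicates 2 and 3. Of 9 CA1 genes 4 fell in Trem2-KO mice, 5 when adjusted over the list alone, led by Wfs1, a membrane protein of the endoplasmic reticulum (-0.53 ± 0.08). The median stood at -0.18 (adjusted p = 0.0283 with an estimated correlation; -0.28 without Trem2-KO 3-month replicate 1). In App-KI Wfs1 was the single CA1 gene that fell (-0.28 ± 0.08), 2 when adjusted over the list alone. The median there was -0.11, with a camera adjusted p = 0.0226, and adjusted p = 0.15 with an estimated correlation, and the call was lost without App-KI 9-month replicate 3 (-0.07). In CA3 genes 2 of 11 fell in Trem2-KO mice, also 2 when adjusted over the list alone, with adjusted p = 0.223 with an estimated correlation, and the median of -0.12 was no longer called without Trem2-KO 3-month replicate 1 (-0.15) or 9-month replicate 1 (-0.07) and was -0.21 without 9-month replicate 3. In App-KI edgeR called 0 CA3 genes, 2 had an unadjusted p under 0.05 and DESeq2 called 0. The median there was -0.11, with a camera adjusted p = 0.0382, and adjusted p = 0.347 with an estimated correlation. That call was lost without App-KI 3-month replicate 2 (-0.08) or 3 (-0.08) or 9-month replicate 1 (-0.08). Of 27 synapse genes 3 fell and 1 rose in Trem2-KO mice, 8 and 1 when adjusted over the list alone (median -0.10, adjusted p = 0.135 with an estimated correlation), with Rims1, an active zone protein, up by 0.51 ± 0.06. In App-KI Nrgn fell and Rims1 rose (0.48 ± 0.06), also 1 and 1 when adjusted over the list alone. The synapse median there was -0.05, with a camera adjusted p = 0.0382, and adjusted p = 0.54 with an estimated correlation. It was no longer called without App-KI 3-month replicate 3 (-0.03) or 9-month replicate 1 (-0.03), and was -0.07 without App-KI 3-month replicate 2. Of 12 dentate granule genes Tdo2 fell in App-KI (-0.53 ± 0.14), also 1 when adjusted over the list alone. The dentate median of 0.0034 and mean of -0.03 differed in sign (camera adjusted p = 0.664). In Trem2-KO mice edgeR called 0 dentate granule genes, 1 had an unadjusted p under 0.05 and DESeq2 called 0, with a median of 0.07 (camera adjusted p = 0.63). In myelinating oligodendrocyte genes 3 of 16 fell in Trem2-KO mice, 6 lower and 2 higher when adjusted over the list alone, led by Opalin (-0.75 ± 0.15). Together they had a median of -0.32 (adjusted p = 0.5 with an estimated correlation). This list was no longer called without Trem2-KO 9-month replicate 3 (-0.26). Astrocyte genes rose in 5 of 16 cases in App-KI, 7 when adjusted over the list alone, and in 7 in Trem2-KO mice, 9 when adjusted over the list alone, with adjusted p = 0.0672 and 0.0515 with an estimated correlation. The water channel Aqp4 rose by 0.58 ± 0.06 and 0.31 ± 0.06, and the App-KI median of 0.11 was 0.18 and 0.06 without App-KI 3-month replicates 1 and 3. In cholesterol synthesis 4 of 24 genes rose in each genotype, with 8 higher and 2 lower, and 6 higher and 1 lower, when adjusted over the list alone and adjusted p = 0.398 and 0.493 with an estimated correlation. Those list calls were lost without App-KI 3-month replicate 3 (0.06) or 9-month replicate 3 (0.04), and without Trem2-KO 3-month replicate 2 (0.06) or 9-month replicate 3 (0.04). The first median of 0.09 was 0.16 without App-KI 3-month replicate 1. With the meningeal score as a covariate, chosen after seeing the data, these lists were no longer called with age in Trem2-KO mice: TCA cycle (0.005), synapse (-0.026), CA3 (-0.05), astrocyte (0.077) and cholesterol synthesis (0.068).

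For some of the lists not described so far, the following holds for genotype at 9 months. Other lists that camera called at the preset correlation in that comparison are not described here. In glycolysis the hexokinase Hk2 (-0.57 ± 0.13), the regulator Pfkfb3 (-0.32 ± 0.07) and the lactate transporter Slc16a3 (-0.96 ± 0.22) fell of 22 genes, also 3 when adjusted over the list alone (median -0.0089, camera adjusted p = 0.26). The dentate granule list had 0 of 12 called by edgeR, 1 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.0757). Of 9 thalamus and habenula genes Lef1 rose by 0.53 ± 0.12 (camera adjusted p = 0.106), also the single call when adjusted over the list alone. The striatum list had 0 of 9 called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.416), and so had the 6 measured erythroid genes (adjusted p = 0.781) and the 3 measured T and NK cell genes (adjusted p = 0.594). With age in App-KI mice, chaperone genes had 1 higher and 1 lower of 22, Atf3 (1.29 ± 0.27) and Ddit3 (-0.39 ± 0.10), both stress-induced transcription factors, also 1 and 1 when adjusted over the list alone. Their median of 0.0069 and mean of 0.02 were positive where camera pointed down (adjusted p = 0.426).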
